A study of Homo sapiens with 12 samples.

How the data were processed

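RNA was measured in SH-SY5Y cells, a human neuroblastoma line, carrying a doxycycline-inducible α-synuclein (α-Syn) construct. Per the labels, cells received doxycycline (1 µg/ml) or none, were treated for 16 h with retinoic acid (RA, 5 µM) or DMSO in medium with 0.1% serum, and were collected 72 h from induction. One passage of the labels gives the RA dose as 1 or 5 µM. Libraries were stranded total RNA from 300 ng, sequenced as paired 150 bp reads. There were 12 libraries, 3 in each of the 4 combinations of RA and doxycycline, and each column of the tables matched 1 library. The labels do not say whether replicates were separate cultures.

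The authors' notes list STAR, GRCh38 and DESeq2 1.14.1, and do not state the read counter, its strand setting or the annotation release. The authors deposited one table of raw counts per Ensembl gene and another of normalized counts, which are the raw counts divided by one size factor per library. The deposited normalized counts differed from raw counts divided by median-of-ratios factors by at most 0.000461 of their value. Of 63942 identifiers listed, 37527 carry a question mark in place of a value in every library, for a reason the deposited tables do not state. Because of these cells the unit of the deposited columns is recorded as other, and the remaining cells are whole-number counts in the first table and size-factor-normalized counts in the second. Of the 26415 entries with values, 44 have no gene identifier. They hold 22670 counts, 0.0119% of all counts, and were left out. Of the other 26371 genes, 32 had no count in any library, 21984 had a symbol and 26252 matched GENCODE release 29 by identifier, which gave positions and gene types. Genes were named by the symbols of a gene name reference, and by GENCODE symbols where it had none.

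A check of units did not accept the columns as counts because of the question marks, so the planned edgeR count model was not run. The data themselves did not prevent it, since the other cells of the raw table are whole-number counts. The fallback, planned for files without raw counts, was used as the main test in its place. It was limma-trend (limma 3.58.1, R 4.3.3) on log2 of the normalized count plus 1, over the 17695 genes with a mean normalized count of 10 or more. One model with 4 group means was fitted to all 12 libraries, with 8 residual degrees of freedom. Genes with a two-sided Benjamini-Hochberg adjusted p below 0.05 were called changed. Errors of log2 changes are standard errors from this model with n = 3 per group, and errors of normalized counts are SDs over 3 libraries. Fold changes, apart from ratios and bounds based on reads, were taken from the model's log2 changes. They can therefore differ from the ratio of the mean normalized counts printed beside them.

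The comparisons were doxycycline against none with RA, doxycycline against none with DMSO, RA against DMSO without doxycycline, RA against DMSO with doxycycline, and the interaction, which is the difference between the doxycycline effects with and without RA. There were 30 gene lists with at least 5 tested members, matched by current or GENCODE symbols. For each list the called members were counted over all genes tested and adjusted over the list alone. Lists were tested with camera (preset correlation 0.01, and with an estimated correlation) and with fry, with Benjamini-Hochberg adjustment over the 30 lists. Camera compares a list with the other genes, while fry asks whether the genes of a list move one way on balance. Adjusted p values given for a list are from camera unless fry is named. Overlaps were compared with those of independent gene lists of the same sizes.

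The named genes were chosen by a rule. Per comparison it takes the 10 largest called changes in each direction with a normalized count of at least 1 CPM-equivalent in the higher group and with library values that do not overlap. It adds up to 4 called members with the smallest p from each list, the 5 genes with the smallest p where fewer than 5 are called, and the 5 RA-responsive genes in each direction with the smallest p. CYP26A1, CYP26B1, RARB, DHRS3, CRABP2, FABP5, TH, RET and the Parkinson disease genes were always included. Some of the named genes are not reported here. TH, SNCB, SNCG, SNCAIP and LAMP3 had no value or fell below the filter and were not analysed here. Comparisons, tests, lists, this rule and the alternatives were fixed before the data were examined, except those named here. The use of the rule and of the lists in the 6 RA libraries alone, the GC correction, the other scalings and the fits without doubted libraries were chosen after seeing the data. For genes with 1 to 3 reads over the 3 libraries of the lower group, the ratio is given with its 95% exact binomial counting interval. Where that group had 0 reads, a lower bound was computed against 3 reads over the group. Intervals and bounds cover counting error only.

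GC correction removed from each library a lowess trend (span 0.3) on gene GC content, for 17624 of the tested genes. The trend was that of log2 values minus the gene's mean over the libraries of all groups. The correction therefore also removes any true difference between groups that goes with GC content. Alternatives fixed in advance were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, limma-voom, the replicate number as a block, a fit of only the libraries compared, an estimated correlation in camera, and leaving out each library in turn. Added alternatives were TMM and total-count scaling, GC correction alone, with only the RA libraries and without DMSO plus doxycycline library 3, and a fit without DMSO plus doxycycline libraries 1 and 2.

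Total counts per library ran from 11016841 to 24023531. The test was checked on simulated data: counts were drawn at the observed means and library sizes, with a wider spread in the groups without RA, and 1.5-fold, 2-fold and 4-fold changes were put on known genes with doxycycline. With RA, the fit of 12 libraries recovered 3%, 65.2% and 96.7% of these changes with 0 false calls. The fit of the 6 RA libraries recovered 69.7%, 80.3% and 100% with 6 false calls. Without RA, the fit of 12 libraries recovered 9 of 66, 46 of 66 and 59 of 61 changes with 39 false calls. False calls made up more than the nominal share of 0.05 there. The simulated spread was independent between genes, with no GC trend and no RA effect. The shares recovered and the false calls therefore need not hold for these data, whose DMSO libraries differ by GC content.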

Results

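Gene-level read counts were measured in SH-SY5Y cells with and without induced α-Syn, the protein that aggregates in Parkinson disease, and with RA, a vitamin A derivative that drives differentiation of neuroblastoma cells, or its vehicle DMSO. The groups were DMSO, DMSO plus doxycycline, RA, and RA plus doxycycline, with 3 libraries each. Total counts were 17551097, 13609806 and 12101964 in the DMSO libraries and 11886546, 11016841 and 18619488 with DMSO plus doxycycline. They were 19763775, 13939453 and 17096845 with RA and 11953153, 18304572 and 24023531 with RA plus doxycycline. Doxycycline and α-Syn always came together, and doxycycline in cells without the construct was not analysed here, so every effect of induction below is that of both.

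The RA libraries lay close together, while the DMSO libraries did not. The median SD per gene on the log2 scale was 0.099 with RA and 0.105 with RA plus doxycycline, against 0.201 with DMSO and 0.326 with DMSO plus doxycycline. The first principal component held 58.1% of the variance and parted RA from DMSO. It also spread the libraries without RA, from -15.3 in DMSO library 1 to -78.5 in DMSO plus doxycycline library 2. The RA libraries lay between 43.1 and 49 on it. The second component held 13.8% and parted DMSO plus doxycycline library 3, at 45.8, from libraries 1 and 2 of its group, at -26.3 and -44.2. This spread went with GC content. Genes in the highest-GC group (the 3525 genes above 57.2% GC) had a median log2 difference from the RA mean of -0.99, -1.20 and -0.06 in the 3 DMSO plus doxycycline libraries. The values were -0.07, -0.43 and -0.40 in the DMSO libraries and between -0.04 and 0.06 in the 6 RA libraries.

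**Figure D1:**
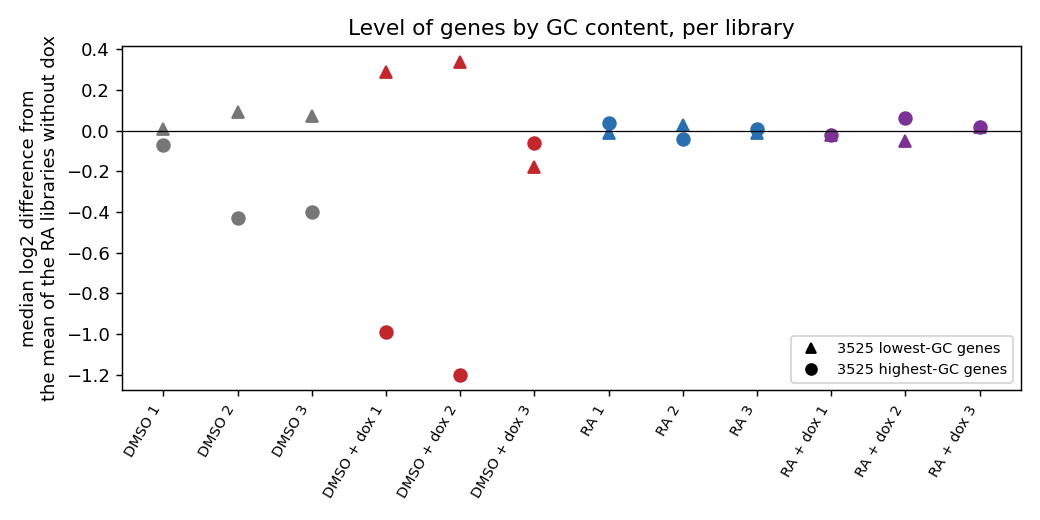
Median log2 difference of the 3525 lowest-GC genes (triangles) and the 3525 highest-GC genes (circles) from the mean of the RA libraries without doxycycline, for each of the 12 libraries. DMSO plus doxycycline libraries 1 and 2 sit at -0.99 and -1.20 for the highest-GC genes, and the RA libraries sit near 0.

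**Figure D2:**
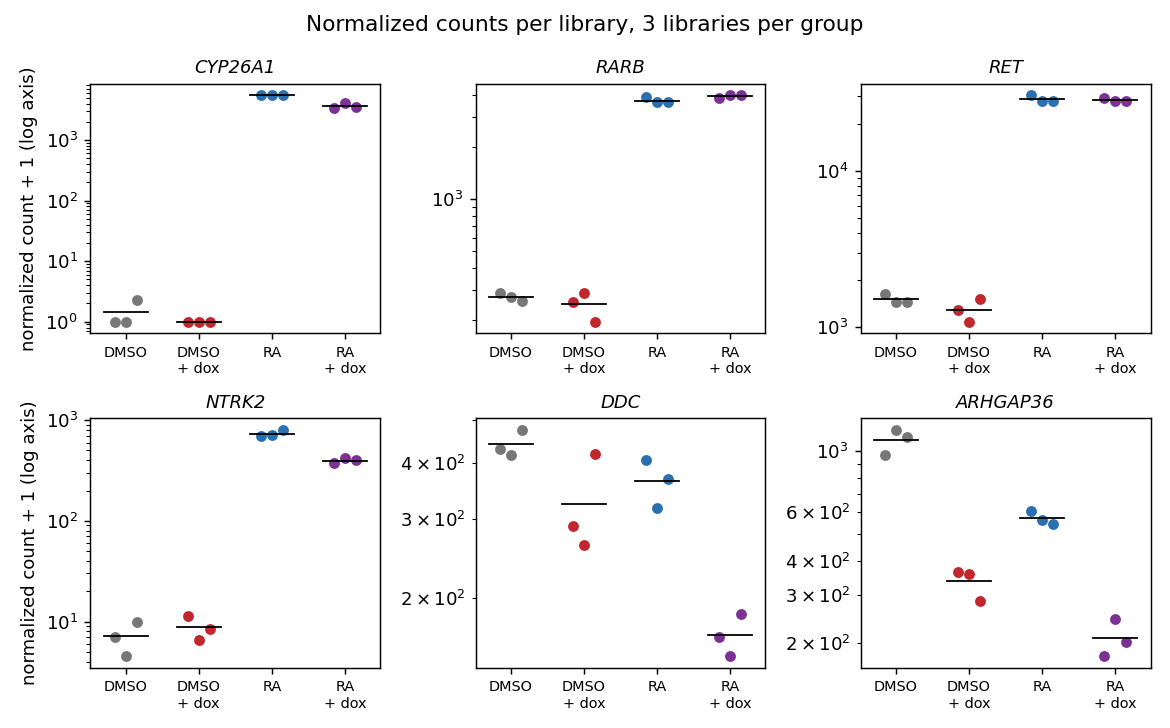
Normalized counts plus 1 on a log axis for 6 genes in each library (points) with the mean of the 3 libraries of each group (bars), by RA and doxycycline. CYP26A1, RARB, RET and NTRK2 are higher in the RA groups, and ARHGAP36 is lower with doxycycline in both.

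The first comparison asked which genes change when α-Syn is induced in cells that also receive RA. ARHGAP36 (chromosome X, 131058242 to 131089883, GRCh38) fell, from 570.8 ± 32.3 to 207.7 ± 33.5 normalized counts (log2 -1.46 ± 0.14, adjusted p = 0.00106). In the fit of 12 libraries 1 gene was higher and 1 lower, and 509 genes had an unadjusted p under 0.05, fewer than the 885 expected by chance. DDC (log2 -1.14 ± 0.17, adjusted p = 0.0839), ECM1 (1.46 ± 0.23, adjusted p = 0.0888) and ADAMTS1 (0.56 ± 0.09, adjusted p = 0.0888) had the next smallest p. When the spread was taken from the 6 RA libraries alone, 346 genes rose and 351 fell, 14 and 18 of them by at least 2-fold, and ARHGAP36 was among them. The fit of 12 libraries without DMSO plus doxycycline library 3 gave 24 higher and 25 lower, and without library 2 of that group 3 and 2. GC correction gave 32 higher and 39 lower.

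From the RA libraries alone, the largest increases included KCNAB1 (log2 2.42 ± 0.51), a potassium channel subunit with a mean of 17.87 ± 5.8 normalized counts after induction, and ECM1 (1.46 ± 0.09), an extracellular matrix protein. ICAM1, an adhesion molecule, rose 2.35-fold from 135.2 ± 9.85 to 318.6 ± 8.53 normalized counts (adjusted p = 2.19e-10). AGT, the angiotensin precursor, rose by 1.26 ± 0.25 and GBP3, a guanylate-binding protein, by 1.23 ± 0.27. APOL6, SMPDL3B, CARNS1 and TDH-AS1 rose by between 1.18 and 1.33. The largest decreases were SMOC1 (-1.84 ± 0.20), a secreted calcium-binding protein, the imprinted non-coding RNA H19 (-1.65 ± 0.20) and TYRP1 (-1.59 ± 0.33), a melanin synthesis enzyme. ECEL1, a neuronal peptidase, fell 2.39-fold (-1.26 ± 0.12, adjusted p = 3.04e-09). NAT2 (-1.47), ANGPT2 (-1.27) and ATP8B1-AS1 (-1.17) also fell. KIF4B (-1.17) and UBA52P6 (-1.29) fell too, but both are near copies of other genes and their reads cannot be assigned with certainty.

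Some genes of the catecholamine phenotype fell in induced RA cells: 3 of 12 members, against 0 higher (1 higher and 3 lower adjusted over the list alone). DDC, which makes dopamine from L-DOPA, fell 2.21-fold from 363.6 ± 44.9 to 163.9 ± 18.2 normalized counts (adjusted p = 1.77e-09). SLC6A2, the noradrenaline transporter, fell by 0.79 ± 0.17 and MAOA by 0.25 ± 0.07 on the log2 scale. TH was not analysed here. The list's adjusted p was 0.00939, and 0.422 with an estimated correlation. Of 28 retinoid metabolism genes 1 rose and 3 fell (2 and 4 adjusted over the list alone). CYP26A1 and CYP26B1, which break down RA, fell by 0.59 ± 0.05 and 0.71 ± 0.10, and CRABP2, which binds RA, fell by 0.22 ± 0.04. Of 28 RA targets 4 rose and 4 fell (9 and 4 adjusted over the list alone). NTRK2, the receptor of brain-derived neurotrophic factor, fell by 0.89 ± 0.07 and PLAT, a plasminogen activator, rose by 0.67 ± 0.06. RARB (0.09 ± 0.05), RET (-0.02 ± 0.05), DHRS3 (-0.05 ± 0.06) and FABP5 (-0.27 ± 0.16) were not called.

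Cell cycle genes fell in 19 of 56 cases and rose in 1 (26 and 6 adjusted over the list alone). TOP2A (-0.42 ± 0.05), KIF20A (-0.42 ± 0.07), UBE2C (-0.40 ± 0.07) and CENPF (-0.32 ± 0.05), which act in mitosis, were among those that fell. The list's adjusted p was 1.61e-07, and 0.422 with an estimated correlation. Among cytosolic ribosomal proteins 11 of 75 fell and 0 rose (31 and 0 adjusted over the list alone), including RPS21 (-0.22 ± 0.05), RPL27A (-0.21 ± 0.04), RPS23 (-0.20 ± 0.04) and RPS3 (-0.18 ± 0.04). That list had an adjusted p of 9.85e-21, and 0.422 with an estimated correlation. Among neuronal differentiation genes 4 of 28 fell and 1 rose (8 and 2 adjusted over the list alone; adjusted p = 0.000692, and 0.422 with an estimated correlation). CHGB (-0.28 ± 0.07) and STMN2 (-0.18 ± 0.05) fell and SCG2 (0.33 ± 0.05) rose.

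Interferon response genes rose in 7 of 30 cases and fell in 0 (12 and 0 adjusted over the list alone). B2M (0.39 ± 0.05), which takes part in antigen presentation, RIGI (0.34 ± 0.06) and IFI6 (0.33 ± 0.07) were among them. The list's adjusted p was 1.61e-07, and 0.422 with an estimated correlation. Lysosome and autophagy genes rose in 9 of 41 cases and fell in 0 (13 and 0 adjusted over the list alone). CTSA (0.32 ± 0.05), NAGLU (0.33 ± 0.08) and SQSTM1 (0.27 ± 0.04) were among these. The adjusted p was 7.92e-07, and 0.422 with an estimated correlation. Of 27 p53 and apoptosis genes 4 rose and 0 fell (5 and 0 adjusted over the list alone), including CDKN1A (0.37 ± 0.05), TNFRSF10B (0.28 ± 0.06), BCL2L11 (0.24 ± 0.07) and ZMAT3 (0.20 ± 0.05). That list's adjusted p was 0.000141, and 0.422 with an estimated correlation.

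Other lists also held called members in the RA libraries. WNT and BMP signalling had 3 higher and 2 lower of 22, among them DKK2 (0.36 ± 0.04), TGFB1 (0.44 ± 0.11), SFRP1 (-0.29 ± 0.05) and FZD7 (-0.23 ± 0.05). Adrenergic transcription factors had 1 higher and 3 lower of 19, with GATA2 at -0.53 ± 0.09, TFAP2B at -0.25 ± 0.05, SOX11 at -0.19 ± 0.05 and TBX2 at 0.21 ± 0.05. Mesenchymal markers had 2 higher and 1 lower of 22, with SOX9 at 0.47 ± 0.09, COL5A1 at 0.25 ± 0.07 and DCN at -0.36 ± 0.08. The ATF4 stress response had 3 higher and 1 lower of 39, with MTHFD1L at 0.34, SLC3A2 at 0.25, SLC1A5 at 0.22 and PSAT1 at -0.36. Glycolysis and hypoxia had 2 higher of 33, PFKFB3 at 0.64 ± 0.08 and P4HA2 at 0.38 ± 0.10. Fatty acid synthesis had 1 higher (SREBF1, 0.24) and 1 lower (SCD5, -0.32) of 26. Immediate early genes had 1 higher (DUSP6, 0.26) and 1 lower (IER5, -0.24) of 20, with a list adjusted p of 0.031, and 0.472 with an estimated correlation.

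Genes called alone in their list included PLCE1 (0.24) among 37 phosphoinositide genes, HSPA8 (0.28) among 23 heat shock genes, MT-RNR2 (0.20) among 14 mitochondrially encoded genes, ACAT2 (-0.20) among 24 cholesterol genes and H4C3 (-0.23) among 22 histone genes. Of these lists, the mitochondrially encoded genes had an adjusted p of 0.0152 (0.528 with an estimated correlation) and the histone genes 0.000183 (0.664). ER unfolded protein response genes had 0 called of 26 (5 higher adjusted over the list alone) and an adjusted p of 0.00284, and 0.456 with an estimated correlation. HOX, synaptic vesicle, Schwann, epithelial, nuclear OXPHOS, mitochondrial ribosome and oxidative stress genes held 0 called members, also adjusted over the list alone. By that count the higher and lower members were 3 and 2 for WNT and BMP, 2 and 3 for adrenergic, 3 and 3 for mesenchymal, 4 and 2 for ATF4, 4 and 0 for glycolysis, 1 and 1 for fatty acid, 6 and 1 for immediate early, 0 and 0 for phosphoinositide, 1 and 0 for heat shock, 1 and 0 for mitochondrially encoded, 0 and 1 for cholesterol and 0 and 1 for histone genes. Median, mean and test differed in sign for the retinoid, synaptic, adrenergic, Schwann, heat shock, mesenchymal and ATF4 lists in at least 1 of the tests, and camera called none of these. In the fit of 12 libraries 9 lists were called with the preset correlation (10 after GC correction) and 0 with an estimated one, where the lowest adjusted p was 0.15.

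**Figure D3:**
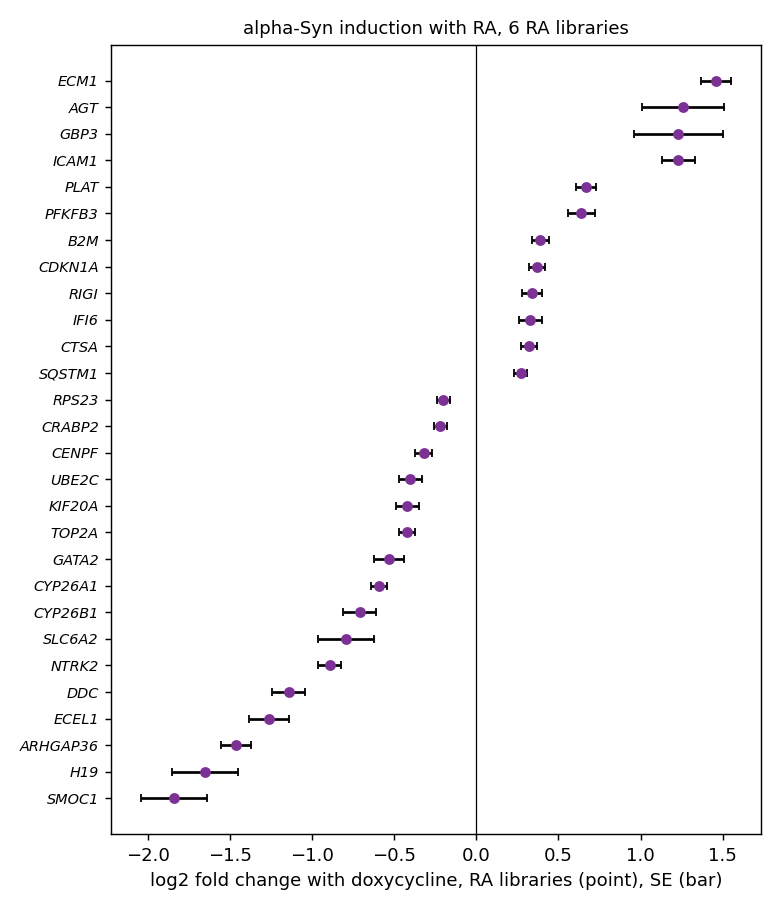
Log2 change with doxycycline in the 6 RA libraries for 28 named genes (points) with the standard error (bars). ECM1, at 1.46, is the highest and SMOC1, at -1.84, the lowest of those drawn.

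The second comparison asked which genes change with α-Syn induction in DMSO. TXNIP, an inhibitor of thioredoxin, rose 1.94-fold from 2789 ± 226 to 5421 ± 686 normalized counts (log2 0.95 ± 0.11, adjusted p = 0.00281). CCL2, a chemokine, rose 1.82-fold from 190 ± 20.1 to 346.7 ± 37.5 (0.86 ± 0.12, adjusted p = 0.0332). ARHGAP36 fell 3.28-fold from 1097 ± 116 to 334.8 ± 43.9 (-1.71 ± 0.14, adjusted p = 0.000161), and HS3ST2, a heparan sulfate sulfotransferase, fell 2.71-fold from 47.26 ± 11 to 16.55 ± 1.71 (-1.44 ± 0.20, adjusted p = 0.0277). CCL2 and HS3ST2 lost their calls with limma-voom (adjusted p = 0.0624 and 0.181), with replicate as a block (0.106 in both), in most fits without a single library and in the fit of only the libraries compared (0.785 in both), and TXNIP lost its call in the last of these (0.565). In all, 3 genes were higher and 2 lower, and 2487 genes had an unadjusted p under 0.05, where 885 are expected by chance. The number rests on DMSO plus doxycycline library 3: without it 2747 genes were higher and 4391 lower, and the highest-GC genes stood at -0.99 and -1.20 in the remaining libraries of the group. After GC correction 57 genes were higher and 60 lower, 4 of the 5 called before among them and HS3ST2 not (-1.07, adjusted p = 0.0815).

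Gene lists without RA held almost no called members. Adjusted over the list alone, 10 of 24 cholesterol genes, 14 of 22 histone genes, 3 of 19 adrenergic factors, 2 of 12 catecholamine genes, 2 of 6 epithelial markers, 1 of 11 HOX genes and 1 of 33 glycolysis genes were lower. By the same count 1 of 28 neuronal and 1 of 56 cell cycle genes were higher. With the preset correlation 10 lists were called: histone (adjusted p = 1.58e-08), cholesterol (1.59e-07), cytosolic ribosomal (0.000679), catecholamine (0.00132), adrenergic (0.00132), glycolysis (0.00132), fatty acid (0.0123), ATF4 (0.0342) and retinoid genes (0.0399) toward lower levels and mitochondrially encoded genes (0.0151) toward higher ones. After GC correction the calls of the ATF4 (0.503), retinoid (0.0501) and mitochondrially encoded genes (0.114) were lost, and the heat shock (0.0195) and lysosome lists (0.0195) were called toward higher and the OXPHOS list (0.0252) toward lower levels. With an estimated correlation 0 lists were called, and the lowest adjusted p was 0.142. Fry called 6 lists, and after GC correction no longer the adrenergic one (adjusted p = 0.0242, then 0.0665). Lists whose median, mean and test differed in sign included the RA target, heat shock, phosphoinositide, cell cycle, p53 and interferon lists, none of which camera called.

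Across 17695 genes, the induction effects with and without RA correlated little (Pearson 0.058, Spearman -0.003, and genes are not independent replicates). ARHGAP36 was called lower in both comparisons (0.000113 expected of independent lists). Of the 697 genes called in the RA libraries alone, 382 (54.8%) had the same sign without RA, against 49.4% of all genes. After GC correction the shares were 69.7% and 52.8%.

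The third comparison asked what RA does in uninduced cells. CYP26A1 (chromosome 10, 93073475 to 93077890) rose from 0.4245 ± 0.735 to 5520 ± 22.2 normalized counts. Its ratio, from 1 read against 18964, was 15400, with a counting interval of 2764 to 608500. DHRS3, which reduces retinal, rose from 1 read to 4604 (ratio 3740, interval 670.9 to 147700). CYP26B1 rose from 3 reads to 1227 (ratio 332.2, interval 113.4 to 1613) and CRABP2 289-fold from 37.6 ± 15.4 to 10440 ± 456 normalized counts (log2 8.18 ± 0.34). RARB, an RA receptor and target, rose 13.7-fold (3.77 ± 0.13), and RET, the receptor of GDNF-family ligands, rose from 1516 ± 110 to 28750 ± 1570 (4.25 ± 0.11, adjusted p = 5.69e-11). NTRK2 rose 108-fold (6.75 ± 0.27).

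Other large increases were GDF10, a BMP-family ligand, from 2 reads to 4777 (ratio 1940, interval 536.8 to 16030), the potassium channel gene KCNJ5 (632, interval 174.7 to 5223), LINC01587 (1061, interval 190.1 to 41930) and REG3G (418.3, interval 115.5 to 3459). PTPRH, a receptor phosphatase, rose by 6.90 ± 0.64 on the log2 scale. The largest decreases were DRGX (-4.16 ± 0.51), ID4, an inhibitor of helix-loop-helix factors (-4.12 ± 0.18, from 1129 ± 173 to 63.7 ± 5.58 normalized counts), HRK, a pro-apoptotic gene (-3.79 ± 0.17), RBM24 (-3.75 ± 0.43), LRRC4 (-3.64 ± 0.27) and KIF26B (-3.59 ± 0.15). ADAMTS17 (-3.52 ± 0.61), RASL11B (-3.46 ± 0.33) and MARCHF11 (-3.39 ± 0.15) followed. CBLN4 fell from 88 reads to 3 (ratio 36.11, interval 11.96 to 178.5). FABP5, which also binds RA, fell by 0.99 ± 0.17.

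In all, 1305 genes rose and 1665 fell, 622 and 421 of them at least 2-fold. Higher genes made up 43.9% of the calls, and 55.7% with total-count scaling. Leaving out DMSO library 2 or 3 or any 1 of the RA libraries without doxycycline gave 790 to 861 higher and 958 to 1054 lower genes, and leaving out DMSO plus doxycycline library 3 gave 3214 and 3264. GC correction gave 2649 and 2912, and 2867 of the 2970 genes called before were called again, all with the same sign.

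The fourth comparison asked the same in induced cells. CYP26A1, with 0 reads in DMSO plus doxycycline, was at least 3338-fold higher with RA, at 3676 ± 358 normalized counts, and REG3G was at least 198-fold higher. GDF10 (ratio 2498, interval 448 to 98680), DHRS3 (1765, interval 488.3 to 14580), CYP26B1 (291.9, interval 80.55 to 2415) and COLCA1 (180.7, interval 32.13 to 7168) rose from 1 or 2 reads. CRABP2 rose by 8.53 ± 0.34, HIC1, a transcriptional repressor, by 7.60 ± 0.78, LINC01587 by 7.50 ± 0.56, KCNJ5 by 7.37 ± 0.61, NTRK2 by 5.53 ± 0.27, RET by 4.46 ± 0.11 and RARB by 4.03 ± 0.13. The largest decreases were ADAMTS17 (-4.61 ± 0.61), OPRK1, the kappa opioid receptor (-4.10 ± 0.52), HRK (-4.05 ± 0.17), ID4 (-3.80 ± 0.18), P2RY1 (-3.72 ± 0.65), LAMP5 (-3.52 ± 0.22), RASL11B (-3.31 ± 0.33) and SLC6A2 (-3.29 ± 0.14). RNY1 (-4.74 ± 0.94) and RN7SL778P (-3.59 ± 0.61) fell as well, but both belong to repeated small RNA families and their reads cannot be assigned with certainty. FABP5 fell by 1.38 ± 0.17.

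With induction 3957 genes rose and 3220 fell, 1584 and 936 of them at least 2-fold. GC correction gave 3580 and 3879, with 720 and 877 at least 2-fold. Leaving out DMSO plus doxycycline library 1 or 2 gave 2465 and 2551 higher genes, leaving out RA plus doxycycline library 2 gave 2555, and leaving out DMSO plus doxycycline library 3 gave 5134 lower genes. The highest-GC genes stood at -0.75 on average in DMSO plus doxycycline and at 0.02 in RA plus doxycycline, and 5018 of the 7177 calls were called again after GC correction, 4964 of them with the same sign. Fits of only the libraries compared gave 4075 calls with induction and 5463 without. That order is the reverse of the 7177 and 2970 calls of the main fit, so which state had more calls depends on the fit. The RA effects with and without induction correlated at 0.837 across genes (Spearman 0.797), with 1109 genes higher in both (291.8 expected of independent lists), 1431 lower in both (303 expected) and 0 opposite.

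Genes of the RA pathway leaned toward higher levels as groups. Of 28 retinoid metabolism genes 9 rose and 5 fell in uninduced and 14 and 5 in induced cells (11 and 6, then 15 and 5, adjusted over the list alone). Adjusted p was 0.00322 and 0.0017, and 0.0368 and 0.0497 with an estimated correlation. Of 28 RA targets 13 rose and 5 fell, then 16 and 4 (15 and 5, then 17 and 6, adjusted over the list alone), with adjusted p of 3.65e-08 and 5.69e-06, and 0.00392 and 0.0133 with an estimated correlation. These lists share members. Of 11 HOX genes 5 rose and 0 fell, then 6 and 1 (the same adjusted over the list alone), with adjusted p of 0.00057 and 0.00674, and 0.0368 and 0.0907 with an estimated correlation. HOXD3 (1.98 ± 0.23 and 3.02 ± 0.23), HOXD8 (1.90 ± 0.13 and 1.72 ± 0.13), HOXD9 (1.48 and 1.84) and HOXD10 (1.42 and 1.78) were among those that rose.

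Among genes of noradrenergic identity and of cell division more fell than rose. Of 19 adrenergic neuroblastoma transcription factors 2 rose and 12 fell in uninduced and 3 and 13 in induced cells (2 and 14, then 3 and 13, adjusted over the list alone). Adjusted p was 1.01e-07 and 0.000478, and 0.0368 and 0.115 with an estimated correlation. MYC fell by 2.95 ± 0.23 and 2.46 ± 0.23, EYA1 by 1.36 ± 0.09 and 1.35 ± 0.09, TFAP2B by 1.13 ± 0.08 and 1.07 ± 0.08 and ISL1 by 0.79 ± 0.08 and 0.82 ± 0.08. Of 12 catecholamine genes 1 rose and 5 fell, then 2 and 5 (the same adjusted over the list alone). SLC6A2 fell 9.02-fold in uninduced cells, from 851.3 ± 40.1 to 93.83 ± 10.8 normalized counts. CYB561 fell by 1.60 ± 0.13 and 1.11 ± 0.13, GCH1, which makes the cofactor of tyrosine hydroxylase, by 1.08 ± 0.11 and 0.88 ± 0.11, DBH, which makes noradrenaline, by 1.31 ± 0.32 in uninduced cells and DDC by 0.95 ± 0.17 in induced ones. Camera did not call that list (adjusted p = 0.0549 and 0.182), and fry called it lower in both states (adjusted p = 0.0001845 and 0.0003522). After GC correction camera called it lower in uninduced cells (0.0415, and 0.149 with an estimated correlation).

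Of 56 cell cycle genes 0 rose and 21 fell, then 0 and 27 (the same adjusted over the list alone), with adjusted p of 8.07e-07 and 4.98e-07, and 0.0392 and 0.0497 with an estimated correlation. CCND1 fell by 1.82 ± 0.13 and 1.55 ± 0.13, CCNE2 by 1.23 ± 0.17 and 1.52 ± 0.17, RRM2 by 1.03 ± 0.12 and 1.27 ± 0.12 and MCM10 by 1.03 ± 0.12 and 1.28 ± 0.12. After GC correction the estimated-correlation calls that held were those of the RA targets (adjusted p = 0.0364) and of the adrenergic factors (0.0364) in uninduced cells, while the adjusted p of the cell cycle list was 0.149 and 0.102, of the retinoid list 0.0987 and 0.0684, of the HOX genes 0.103 and 0.175 and of the RA targets in induced cells 0.0528.

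Interferon response genes rose in 11 of 30 cases, then 20, and fell in 0 (17 and 21 higher adjusted over the list alone). After GC correction 20 rose in uninduced and 22 in induced cells, and 0 fell. Adjusted p was 4.24e-06 and 1.16e-05, and 0.0815 and 0.111 with an estimated correlation. IRF9 (1.53 ± 0.19 and 1.22 ± 0.19), IFIT1 (1.46 ± 0.22 and 1.76 ± 0.22), IRF1 (0.96 and 0.99) and HLA-E (0.91 and 1.32) were among them. Lysosome and autophagy genes rose in 5 of 41 cases and fell in 2, then 18 and 2 (5 and 2, then 20 and 3, adjusted over the list alone). After GC correction these counts were 12 and 2, then 17 and 3. CTSA (1.04 and 1.36), CTSB (0.96 and 1.08), SMPD1 (0.96 and 1.40) and SQSTM1 (0.73 and 1.09) rose. Adjusted p was 0.04996 and 0.0197, and 0.375 and 0.446 with an estimated correlation. Fatty acid genes rose in 6 of 26 cases and fell in 3, then 14 and 3 (8 and 5, then 15 and 4, adjusted over the list alone), with SCD (0.75 and 1.13), ACSL3 (0.79 and 0.84) and ELOVL5 (0.82 and 0.91) rising. Adjusted p was 0.0842 and 0.0197, and 0.22 and 0.115 with an estimated correlation. After GC correction it was 0.0181 in uninduced cells, and 0.309 with an estimated correlation. The fatty acid genes called higher and lower were then 11 and 6 in uninduced and 16 and 4 in induced cells.

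Neuronal genes went both ways with RA. Of 28 neuronal differentiation genes 4 rose and 11 fell, then 5 and 10, with the same counts adjusted over the list alone. SCG2 rose by 2.26 ± 0.16 and 1.77 ± 0.16, while ELAVL4 fell by 1.36 ± 0.11 and 1.45 ± 0.11 and STMN2 by 1.09 ± 0.12 and 1.37 ± 0.12. Of 29 synaptic vesicle genes 7 rose and 3 fell, then 11 and 4 (8 and 3, then 15 and 5, adjusted over the list alone). SNAP25 (1.38 and 1.19) and DNM3 (2.30 and 2.07) rose and SYT4 (-1.22 and -1.30) and SYN2 (-1.09 and -1.21) fell. Of 22 mesenchymal markers 3 rose and 8 fell, then 7 and 8, among them VIM (-1.29 and -1.24), COL1A2 (-2.55 and -2.40) and PDGFRA (-1.46 and -1.56), with DCN lower in uninduced cells (-1.28) and SOX9 higher in induced ones (1.45). Of 22 WNT and BMP genes 5 rose and 2 fell, then 8 and 3. The WNT antagonists SFRP1 (1.98 in induced cells) and DKK2 (1.78 and 1.90) and the receptor FZD7 (2.10 and 2.26) rose, while SMAD9 (-1.18) fell in uninduced and LGR5 (-1.17) in induced cells. Camera called none of these 4 lists. After GC correction it called neuronal differentiation lower in both states (adjusted p = 0.0276 and 0.0407, with 4 members higher and 14 lower, then 5 and 14) and mesenchymal markers lower in uninduced cells (0.0276, with 5 higher and 10 lower). With an estimated correlation these were 0.309, 0.342 and 0.149.

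Metabolic and stress lists were mixed. Of 24 cholesterol genes 0 rose and 5 fell in uninduced cells, among them HMGCS1 (-0.75), ACAT2 (-0.54), SQLE (-0.43) and FDFT1 (-0.36). In induced cells 10 rose and 4 fell, with TM7SF2 (1.20), DHCR7 (1.13) and INSIG1 (0.83) higher. Of 33 glycolysis and hypoxia genes 1 rose and 4 fell, then 10 and 6, with HK2 (-1.39 and -1.18) and LDHA (-0.94 and -1.06) lower in both, ENO1 (-0.66) in uninduced cells, GPI (0.55 and 0.92) higher in both and PFKFB4 (1.11) in induced cells. Of 39 ATF4 genes 7 rose and 6 fell, then 9 and 5 (8 and 13, then 6 and 12, after GC correction), with DDIT4 (2.28 and 2.70), ATF3 (2.14 and 2.24) and SLC1A4 (1.03 and 1.17) higher, MTHFD2 (-0.74) lower in uninduced cells and PHGDH (1.17) higher in induced ones. Of 23 heat shock genes 3 rose and 10 fell, then 6 and 13, among them HSPA8 (-0.81 and -0.81) and HSPD1 (-0.61 and -0.81). HSP90AB1 (-0.54) and STIP1 (-0.43) fell in uninduced cells and DNAJA1 (-0.82) and AHSA1 (-0.59) in induced ones. Of 26 ER unfolded protein response genes 0 rose and 3 fell, then 5 and 6, with EIF2AK3 (-0.78 and -0.88) and CREB3L2 (-0.63 and -0.50) lower in both, SEC24D (-0.46) in uninduced cells and PDIA3 (-0.56) and HSP90B1 (-0.63) in induced ones. Camera called none of these 5 lists. After GC correction it called heat shock genes lower in both states (adjusted p = 0.0121 and 0.00274, with 3 members higher and 13 lower, then 4 and 15), and 0.396 and 0.359 were the values with an estimated correlation. The cholesterol counts were then 2 higher and 9 lower in uninduced and 8 and 3 in induced cells.

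Of 86 mitochondrial ribosome genes 0 rose and 13 fell, then 14 and 22, with MRPL3 (-0.74 and -0.83) and MRPL15 (-0.70 and -0.65) lower in both. The list's adjusted p was 0.0322 in uninduced cells, and 0.22 with an estimated correlation. Of 75 cytosolic ribosomal proteins 0 rose and 8 fell, then 17 and 28, with RPL22 (-0.50 and -0.65) lower in both. The adjusted p was 0.04996 in uninduced cells, 0.642 with an estimated correlation and 0.0831 after GC correction. Of 72 nuclear OXPHOS genes 0 rose and 3 fell, then 18 and 17, with NDUFS5 (-0.58 and -0.52) and COX7A2 (-0.46 and -0.54) lower in both. Of 14 mitochondrially encoded genes 0 were called in uninduced cells, and MT-ND2 (-0.79) and MT-CO2 (-0.59) fell in induced ones. Of 24 oxidative stress genes 3 rose and 1 fell, then 11 and 2 (8 and 2, then 8 and 3, after GC correction). NQO1 (0.91 and 0.90) and MT2A (1.97 in induced cells) were higher and TXN (-0.47 and -0.67) lower. Of 27 p53 and apoptosis genes 3 rose and 5 fell, then 7 and 3, with BTG2 (1.08 and 1.00) and CASP9 (0.75 and 0.94) higher. Of 20 immediate early genes 4 rose and 4 fell, then 6 and 3 (4 and 8, then 6 and 7, after GC correction), with DUSP6 (0.60 in uninduced cells) higher in both, KLF6 (-1.28 in induced cells) lower in both, JUN (-1.29) lower in uninduced cells and DUSP5 (0.97) higher in induced ones. Apart from the 2 ribosomal lists in uninduced cells, camera called none of these lists.

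Of 37 phosphoinositide genes 4 rose and 5 fell, then 8 and 8, with INPP5A (0.38 and 0.75) higher and PLCB4 (-1.30 and -1.65) lower. Of 23 Parkinson disease genes 2 rose and 2 fell in uninduced cells, among them PINK1 (0.68 ± 0.19), SYNJ1 (0.46 ± 0.14) and UCHL1 (-0.31 ± 0.10). In induced cells 5 rose and 1 fell, among them PINK1 (1.00 ± 0.19), ATP13A2 (1.20 ± 0.24), PLA2G6 (0.99 ± 0.30), GAK (0.74 ± 0.23) and PARK7 (-0.24 ± 0.09). After GC correction the log2 changes of PLA2G6, GAK and PARK7 were 0.23, -0.03 and -0.03, none called, and with DMSO plus doxycycline library 3 also left out that of PARK7 was 0.07. Of 22 histone genes 0 rose and 1 fell (H2BC5, -0.49), then 2 rose (among them H2AC4, 0.71) and 0 fell. After GC correction 1 rose and 7 fell, then 1 and 6, camera called the list lower in uninduced cells (adjusted p = 0.01695, and 0.683 with an estimated correlation), and H2AC4 in induced cells stood at 0.02, and at -0.03 without DMSO plus doxycycline libraries 1 and 2. Of 5 Schwann and glial markers ERBB3 (0.90) rose and PMP22 (-0.59) fell in uninduced cells, and 0 were called in induced ones. Of 6 epithelial markers 0 were called, then 1 rose (KRT19, 2.25 ± 0.69). Camera called none of these 5 lists without GC correction.

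Adjusted over the list alone, the members higher and lower with RA in uninduced and then in induced cells were 5 and 8, then 7 and 9 for mesenchymal, 6 and 3, then 8 and 3 for WNT and BMP, 1 and 5, then 12 and 4 for cholesterol, and 1 and 4, then 12 and 6 for glycolysis genes. They were 7 and 7, then 9 and 5 for ATF4, 4 and 13, then 7 and 14 for heat shock, 0 and 3, then 5 and 6 for ER unfolded protein response, and 0 and 12, then 14 and 23 for mitochondrial ribosome genes. They were 0 and 2, then 18 and 29 for cytosolic ribosomal, 0 and 3, then 18 and 17 for OXPHOS, 0 and 0 in both for mitochondrially encoded, and 4 and 2, then 11 and 3 for oxidative stress genes. They were 3 and 5, then 7 and 3 for p53, 4 and 6, then 6 and 3 for immediate early, 4 and 5, then 8 and 8 for phosphoinositide, and 3 and 2, then 4 and 0 for Parkinson disease genes. They were 0 and 0, then 1 and 0 for histone, 2 and 1, then 0 and 0 for Schwann, and 0 and 0, then 1 and 0 for epithelial genes. Fry called more lists with RA than camera did, 16 of 30 in uninduced and 21 in induced cells. In both states it called the retinoid, RA target, HOX, synaptic, WNT and BMP, fatty acid, interferon, lysosome and oxidative stress lists higher and the adrenergic, catecholamine, cell cycle, heat shock, mesenchymal and mitochondrial ribosome lists lower. It called the ER unfolded protein response lower in uninduced cells. In induced cells it called neuronal differentiation lower and the ATF4, Parkinson disease, cholesterol, epithelial and immediate early lists higher. After GC correction these 5 higher calls were lost, with fry adjusted p of 0.756 for ATF4, 0.0523 for Parkinson disease, 0.138 for cholesterol, 0.0873 for epithelial and 0.32 for immediate early genes, and so was that of the ER unfolded protein response (0.0814). Fry calls gained by the correction, all lower in uninduced cells, were those of neuronal differentiation (0.00514), phosphoinositide (0.00468), cholesterol (0.0409) and glycolysis genes (0.0103).

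In the RA comparisons median, mean and test differed in sign for the neuronal, ATF4, Schwann, immediate early, catecholamine, mesenchymal, phosphoinositide, OXPHOS, mitochondrial ribosome and cytosolic ribosomal lists in at least 1 of both states.

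**Figure D4:**
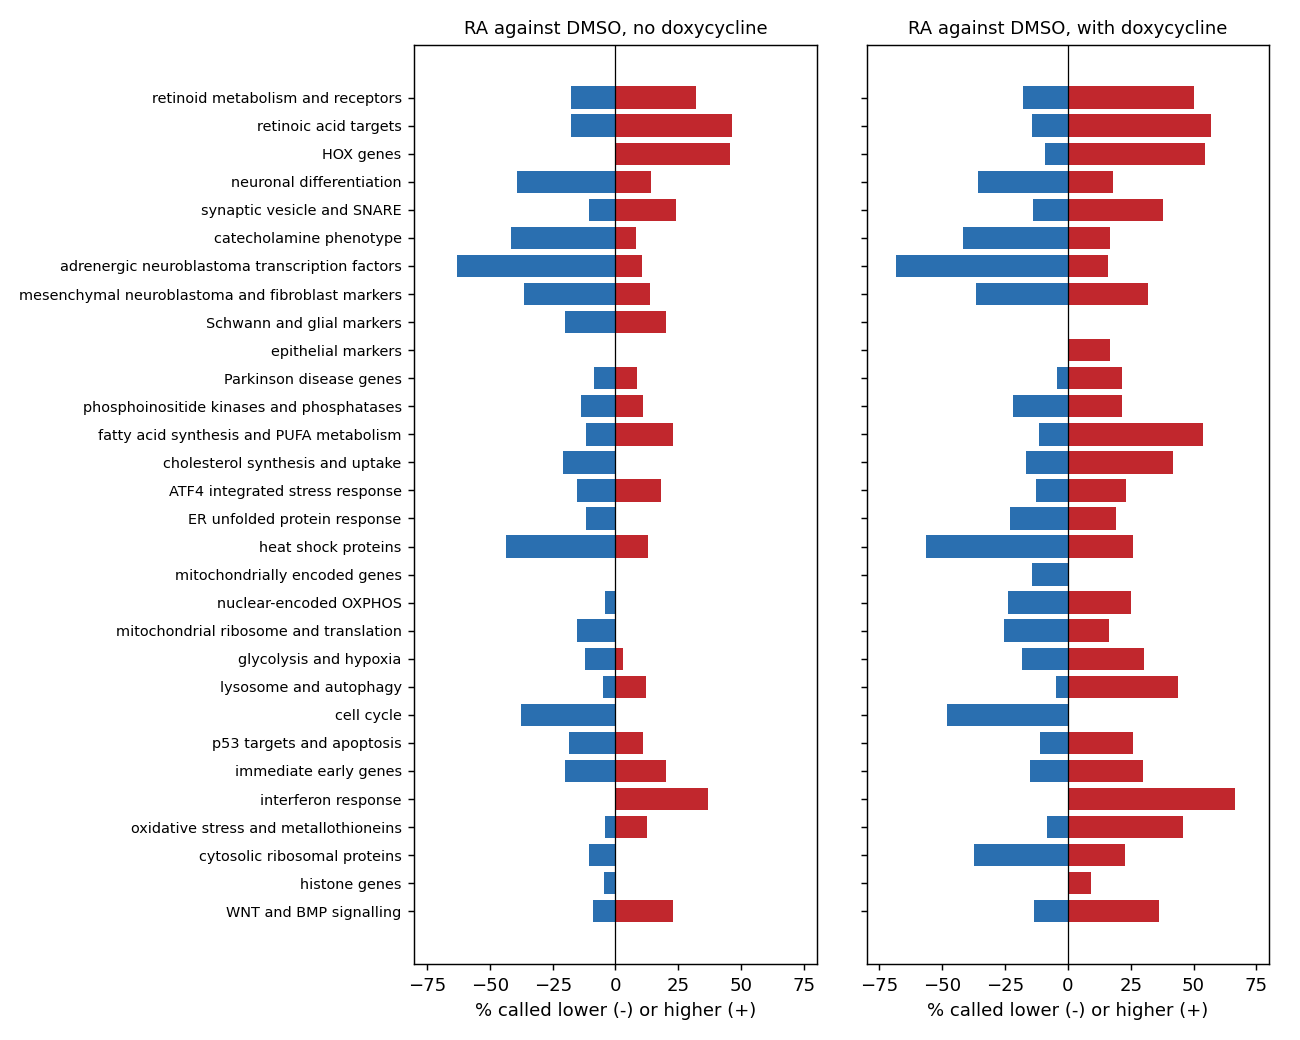
Share of the tested members of each of 30 gene lists called higher (bars to the right) or lower (bars to the left) with RA, in percent, in uninduced (left) and induced cells (right). Adrenergic factors (12 of 19, then 13 of 19 lower) and interferon genes (11 of 30, then 20 of 30 higher) have long bars in both panels. The shares are those without GC correction, after which 20, then 22 of the 30 interferon genes were higher.

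The interaction asked whether α-Syn induction changes the response to RA, or RA the response to induction. No single gene passed: 0 were higher and 0 lower with limma-trend, 954 had an unadjusted p under 0.05 where 885 are expected by chance, and limma-voom also gave 0. The smallest p belonged to PLXNA2, a semaphorin receptor (1.23 ± 0.21), PLXNA4 (0.59 ± 0.13), TXNIP (-0.69 ± 0.15), GALNT4 (3.08 ± 0.70) and RN7SKP178 (-1.75 ± 0.35), each with an adjusted p of 0.712. For the main RA genes the estimates were -0.20 ± 0.38 (CYP26A1), -0.65 ± 0.60 (CYP26B1), 0.25 ± 0.18 (RARB), 0.21 ± 0.16 (RET), -0.47 ± 0.51 (DHRS3), 0.35 ± 0.48 (CRABP2) and -0.38 ± 0.24 (FABP5). They were -0.27 ± 0.24 for HRK, 0.15 ± 0.21 for MARCHF11, -0.11 ± 0.20 for SLC6A2, 0.24 ± 0.12 for ENC1, -0.13 ± 0.14 for KCNH1 and -0.07 ± 0.15 for CHRM2. CYP26A1, CYP26B1 and DHRS3 had at most 3 reads per group without RA. Their interaction estimates therefore rest in part on the pseudocount. The count of 0 rests on DMSO plus doxycycline library 3: without it 3482 genes were higher and 1325 lower. The highest-GC genes stood at -0.99 and -1.20 in the remaining libraries of that group. GC correction of all 12 libraries gave 1 higher and 1 lower gene. With that library also left out, the corrected counts stayed far below 3482 and 1325 but rose far above 1 and 1. The count thus depended on that library after correction too.

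Averaged over both doxycycline states, RA raised 4423 genes and lowered 4019. In the interaction the genes raised by RA had a median of 0.323, positive for 80% of them, and those lowered by RA a median of -0.115, negative for 2887 of them. Camera gave p = 1.29e-16 and 2.03e-15, and 0.135 and 0.113 with an estimated correlation, and fry gave 0.173 and 0.297. After GC correction the medians were 0.074 and -0.059. Both sets were picked by the averaged RA effect, which is independent of the interaction only if the groups vary equally. The median SD was 0.326 with DMSO plus doxycycline and 0.201 with DMSO before the correction. Chance or GC-linked deviations in DMSO plus doxycycline thus favoured both signs in advance, so the medians do not show that induction changed the RA response. Of the 30 lists, 7 were called with the preset correlation and 0 with an estimated one (lowest adjusted p 0.316): cholesterol (2.78e-05), histone (0.000102), glycolysis (0.000773), immediate early (0.0178), fatty acid (0.0187) and adrenergic genes (0.0498) toward higher values and cell cycle genes (0.0178) toward lower ones. After GC correction the calls of the immediate early (0.228) and adrenergic genes (0.399) were lost. No list member was called over all genes tested.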

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

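The tests of spread, GC content, RA-cell RNA and scaling, and the interactions after GC correction and of NTRK2, were chosen only after the result was seen, and the tests of the ATF4 list and of GC content on CYP26A1, CYP26B1 and NTRK2 rest on the RA-libraries-alone fit of the lists and on the GC correction, which were chosen after seeing the data.

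Genes without an identifier held 22670 counts over the 12 libraries, from 1159 to 3058 per library, and were not used in any comparison. Fry called the interaction of the retinoid and of the cholesterol list (adjusted p = 0.0484 in both), and camera with an estimated correlation did not (0.586 and 0.316). After GC correction fry did not call them either (0.221 in both), as the medians went from 0.182 to 0.074 and from 0.424 to 0.288. The genes raised by RA had a median interaction of 0.323 and those lowered by RA one of -0.115, which pass camera with the preset correlation but not with an estimated one (p = 0.135 and 0.113). The way these genes were picked favoured both signs in advance, because the DMSO plus doxycycline libraries varied most. After GC correction 2 genes differed between the induction effects with and without RA. PLXNA2 had an interaction of 1.02 ± 0.13, with 0.61 with RA and -0.42 without it, and TXNIP one of -0.61 ± 0.08, with 0.26 with RA and 0.88 without it (adjusted p = 0.00567 in both).

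For induction with RA, 12 libraries gave 2 genes and the RA libraries alone 697. A GC trend among the RA libraries does not account for the larger number, since GC correction left 799 genes. The wider spread of the DMSO libraries is consistent with the smaller one: the lower of their median SDs was 0.201 and the higher of those with RA 0.105. Whether the 697 genes respond to α-Syn or to doxycycline itself cannot be told apart, because the design gives both together. The ATF4 list, chosen as a sign of a stress response to doxycycline, had a median log2 change of -0.008 over members that went both ways. By the rule written for this test, a median of 0 or below counted against such a response. The median met that rule by no more than its standard error, a margin that was not in the rule. It thus leaves open whether doxycycline itself acted.

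The DMSO libraries stood apart from each other more than the RA libraries did. RNA from RA-treated cells in DMSO library 1 and DMSO plus doxycycline library 3 was looked for in 37 genes at least 16-fold higher with RA. Their median level was 1.275% of that with RA in DMSO library 1, against 0% and 0.09713% in libraries 2 and 3. In DMSO plus doxycycline library 3 it was 0.4294%, against 0.1464% and 0.9941% in libraries 1 and 2. The genes were picked with these libraries in the group means. Low levels were thus favoured in advance, and the values do not exclude such RNA. A GC content bias is consistent with much of the spread, since GC correction brought the median SD of DMSO plus doxycycline from 0.326 to 0.172. That value stays above the 0.098 of RA plus doxycycline, and the source of the rest was not tested. No batch label is given and no biological explanation was tested.

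With RA, induction lowered CYP26A1, CYP26B1 and NTRK2, by a mean log2 change of -0.729 ± 0.044 in the RA libraries alone. Library scaling does not account for this, since the mean was -0.72 with TMM and -0.738 with total-count scaling, nor does GC content, since it was -0.74 after GC correction. A weaker response to RA as a whole is argued against by the 1034 genes at least 2-fold higher with RA, which had a median change of 0.026 (quartiles -0.116 and 0.173), with 45 called lower and 62 higher. Effects of α-Syn or of doxycycline on these genes may underlie the pattern and stay open as untested hypotheses. Whether the effect depends on RA stays open. CYP26A1 and CYP26B1 had at most 3 reads per group without RA. NTRK2, with 17 and 21 reads there, had an interaction of -1.218 ± 0.384 (adjusted p = 0.712).

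Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. For induction with RA the real split gave 2 genes and the highest other 0, with 1 split as large, and in the RA libraries alone the numbers were 697 and 0, with 1 split as large. RA against DMSO gave 2970 genes without and 7177 with induction, with 0 for the highest other split and 1 split as large in both. For induction without RA the real split gave 5 genes and 3 splits gave as many. The split of DMSO libraries 1 and 3 with DMSO plus doxycycline library 3 against the rest gave 6036, and that of DMSO libraries 1 and 2 with the same library 4725, which points to a structure of the samples other than doxycycline. For the interaction the real count is 0, so all 100 of 100 splits drawn give at least as many whatever the data, and the splits decide nothing about it. The highest of the other splits gave 1075 genes, which points to a structure of the samples.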

How the results depend on the processing

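The GC correction, TMM and total-count scaling, and the fits without DMSO plus doxycycline libraries 1 and 2 were chosen only after the results were seen. The edgeR and DESeq2 tests, edgeR on recovered reads and the CPM filter were planned but not run. The columns were not accepted as counts, although the raw table holds whole-number counts. Of 238 called results of the named genes reported here, 199 were called with the same sign in every alternative run and 4 reversed in at least 1. All 238 are calls of the fit of 12 libraries, and calls made in the RA libraries alone are not among them. The fit of the RA libraries alone was repeated only with GC correction and, for CYP26A1, CYP26B1 and NTRK2, with the other scalings. Counts below are given as higher and lower genes, and except where fewer libraries or a narrower spread of the fit make the difference, the cause was not tested. Depth limits the ratios of genes where 1 to 3 reads stand behind the lower group.

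For induction with RA, limma-voom gave 6 and 5, a pseudocount of 5 gave 2 lower, and replicate as a block gave 2 lower. Only the libraries compared gave 346 and 351, with GC correction 368 and 431. For induction without RA, with 3 and 2, limma-voom and the block each gave 2 and 1, most fits without a single library gave 2 higher, the libraries compared gave 1 and 1, and the stricter filter gave 4 lower. Only the libraries compared gave 2730 and 2733 for RA without and 2034 and 2041 for RA with induction, the reverse of the order in the main fit.

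GC correction gave 32 and 39 for induction with RA, 57 and 60 without, 2649 and 2912 for RA without induction, 3580 and 3879 for RA with induction and 1 and 1 for the interaction. With DMSO plus doxycycline library 3 also left out the numbers were 78 and 100, 721 and 1011, 3099 and 3343, 3947 and 4058, and 212 and 119. Without DMSO plus doxycycline libraries 1 and 2 they were 24 and 22, 145 and 376, 3313 and 3207, 2413 and 2067 for RA with induction, and 13 and 18 for the interaction. There the lone remaining library is assumed to vary like the other groups.

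Leaving out each library in turn gave 1 to 24 and 1 to 25 genes for induction with RA, 2 to 2747 and 1 to 4391 without, 790 to 3214 and 958 to 3264 for RA without induction, 2465 to 5735 and 2242 to 5134 for RA with induction, and 0 to 3482 and 0 to 1325 for the interaction. The highest of each came without DMSO plus doxycycline library 3. Called lists ranged over 8 to 11, 6 to 11, 7 to 12, 8 to 10 and 4 to 9, the medians of RA-responsive genes over 0.18 to 0.585 and -0.239 to -0.039, and the correlations over -0.009 to 0.102 for induction and 0.779 to 0.859 for RA.

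With an estimated correlation 0, 0, 5, 3 and 0 lists were called in the 5 comparisons, and the medians of RA-responsive genes, 0.323 and -0.115, lost their call. GC correction gave 14 lists for RA without induction. Without DMSO plus doxycycline libraries 1 and 2 there were 2 lists for induction without RA, 13 for RA with induction and 4 for the interaction. The correlation of the induction effects was 0.021 with no filter and 0.107 with GC correction, with or without library 3. That of the RA effects was 0.654 with no filter, 0.896 with the stricter filter, 0.753 without libraries 1 and 2 and 0.813 with GC correction without library 3.

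These reversed with GC correction, the second value with library 3 also left out: HTRA2 for RA without (-0.26 and -0.26) and with induction (-0.55 and -0.67), GAK (-0.03 and -0.01) and EIF4G1 (-0.20 and -0.28), both for RA with induction. With both changes HTRA2 (0.42) and UCHL1 (0.36) reversed for induction without RA, UCHL1 (-0.35) in the interaction, GAK (-0.16) for RA without induction, and PLCB3 (-0.01), PARK7 (0.07) and MAPT (-0.61) for RA with induction. H2AC4 (-0.03) reversed for RA with induction without libraries 1 and 2.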

Other observations

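The tests below, which use GC-corrected values, were chosen only after the results without correction were seen. After GC correction 12 genes were called higher with induction both with and without RA (0.104 expected of independent lists) and 10 lower in both (0.133 expected), with 1 opposite, PLXNA2. The higher genes included ICAM1, an adhesion molecule (log2 1.21 ± 0.18 with RA and 1.56 ± 0.18 without), ECM1 (1.44 ± 0.13 and 0.88 ± 0.13), CLU, a secreted chaperone (0.92 ± 0.11 and 0.59 ± 0.11), GPNMB (0.80 ± 0.11 and 0.61 ± 0.11), TIMP1, an inhibitor of matrix metalloproteinases (0.70 ± 0.09 and 0.57 ± 0.09), and ADAMTS1, a secreted protease (0.55 ± 0.07 and 0.38 ± 0.07). ABI3BP (0.50 and 0.46), VGF (0.42 and 0.36), B2M (0.40 and 0.29), PAM (0.35 and 0.37) and ITGA7 (0.34 and 0.42) were also higher. The lower genes were ARHGAP36 (-1.48 ± 0.12 and -1.65 ± 0.12), IGFBP5, a secreted binder of insulin-like growth factors (-0.81 ± 0.09 and -0.60 ± 0.09), PACSIN3 (-0.71 and -0.73), NELL2 (-0.56 and -0.45), C11orf96 (-0.49 and -0.48), ITM2A (-0.45 and -0.40), ACTG1, a cytoplasmic actin (-0.35 and -0.40), MBNL3 (-0.34 and -0.38), FAM163A (-0.33 and -0.32) and PDE3A (-0.31 and -0.39).

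The other genes with a small p for induction without RA after GC correction included VCAM1, an adhesion molecule (log2 2.16 ± 0.38, adjusted p = 0.0109), SPP1, a secreted phosphoprotein (2.75 ± 0.50, adjusted p = 0.0136), SCG2 (0.74 ± 0.09, adjusted p = 0.000664) and DBH (-1.17 ± 0.20, adjusted p = 0.00856). These were picked after their values were seen.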
